A study of Mus musculus with 6 samples.

How the data were processed

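Single nuclei were isolated from mouse kidneys with part of the cortex removed, and RNA was counted in 6 libraries, 1 for each of the ages P0, P2, P7, P14, P21 and 6 weeks; per the labels, each library pooled 4 wild-type mice, 2 male and 2 female. The deposited values are whole-number UMI counts per gene and barcode for 32285 genes, made by the authors with Cell Ranger and not scaled further; per the file headers the P2 file comes from version 5.0.1 and the others from "Cell Ranger 4", while the submitters' processing notes name Cell Ranger 5.0.1 and the mm10 genome for all. Whether reads in introns were counted is not stated. Of the files, 5 hold all 6794880 barcodes of the kit, empty droplets included, and the P2 file holds 12216 barcodes chosen before deposit. No column was left without a sample, and all 6 libraries were used.

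A barcode was kept as a nucleus with at least 1000 UMIs, at least 500 genes, at most 5% mitochondrial UMIs and at least 10% of the UMIs of the 100th deepest barcode of its library. That last limit came to 2279.8, 3112.3, 2602.1, 2030.9, 2496 and 2372.7 UMIs from P0 to 6 weeks and set the depth in every library. Doublet scores were computed per library with Scrublet as built into scanpy, and the highest 0.8% for each 1000 barcodes kept were removed: 298, 545, 508, 407, 270 and 570. Scrublet's own threshold would have called 1279, 2067, 1651, 1596, 1 and 1977, and was not used. The nuclei kept held 38.91%, 77.45%, 42.77%, 37.81%, 38.5% and 47.86% of all deposited UMIs, with medians of 2388, 2729, 2505, 2135, 2349 and 2251 genes per nucleus. A count of 0 nuclei is given with the share that 3 nuclei would make.

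The 6 libraries were clustered together with scanpy 1.11.5 (3000 variable genes, 40 components, 20 neighbours, Leiden resolution 2 with leidenalg 0.10.2), which gave 85 clusters. Each cluster was scored against marker genes of the cell types, as fold over the median cluster, and needed 4 markers at least 2-fold up. Clusters that scored for more than 1 type were set apart as mixed (22), and clusters without a clear type were left unnamed (7). A class name such as proximal tubule stands for nuclei that resemble that type by these markers. The naming rule went through 4 versions after the clusters had been seen: the reference was changed from mean to median, the number of markers was raised from 3, a mixed class was added, macula densa was merged with the thick ascending limb and the distal convoluted with the connecting tubule, and clusters whose leading genes pointed to another type were left unnamed. The strictest version was used, and the more lenient one before it was kept as an alternative. The merge also made the thick ascending limb large enough at P0 to be tested.

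Shares of nuclei per class were compared over the 6 libraries with log2 of the postnatal day plus 1, with 6 weeks taken as 42 days, by Pearson's r and Spearman's rho. Their p-values are exact over the 720 orders of the ages and were adjusted by Benjamini-Hochberg over 15 classes. The smallest possible exact p is 0.00139 for r and 0.00278 for rho, and 0.0333 and 0.0667 for a class with 4 libraries at 0. Cycling nuclei were those with at least 2 UMIs of 24 cell cycle genes after random thinning of each nucleus to 2000 UMIs. The share that free RNA alone would give was computed as a Poisson chance from the empty-droplet level of these genes and the highest free RNA share of any class.

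For gene trends, UMIs were summed over the nuclei of a class in each library. In classes with at least 30 nuclei in every library, edgeR 4.0.16 was run in R 4.3.3 with TMM scaling, filterByExpr and the quasi-likelihood test on log2 of day plus 1, adjusted by Benjamini-Hochberg over the genes of a class at 0.05, with 4 residual degrees of freedom. A straight line misses genes that peak at a middle age. DESeq2 1.42.0 was run on the same sums. Sets were tested with camera in limma 3.58.1, with the preset correlation of 0.01 and with an estimated correlation, adjusted over 70 set tests; 48 passed with the preset and 0 with the estimate, where the smallest adjusted p was 0.226. The pipeline was tested on simulated counts with 50 genes changed at each of 2-, 4-, 8- and 16-fold. In proximal tubule edgeR recovered 0%, 20%, 76% and 88% with 3 false calls of 95 (DESeq2 0%, 26%, 78% and 90%, 13 of 110), and in intercalated cells 12%, 52%, 90% and 98% with 4 of 130 (DESeq2 8%, 38%, 84% and 94%, 2 of 114).

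The following were set before the data were examined: the filters, the clustering settings, the markers, the tests, most alternatives, the gene lists and the rule for naming genes. That rule takes, per class, genes past the trend test with a fitted change of at least 2-fold from day 0 to day 42. They must be lower, or higher, in both P0 and P2 than in both P21 and 6 weeks, reach a CPM of 20 in the higher pair, and have a CPM in the class of at least 0.333 of the highest over classes. The 8 largest rises and the 8 largest falls are taken, without mitochondrial, ribosomal, haemoglobin, Xist, Y-linked and unnamed genes. To these come 2 to 4 members of each list with the largest change, textbook members with their values, and cell type markers. The text names those of the resulting 258 gene and class pairs that describe a class best, chosen with their behaviour under the alternatives in view.

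The lists tested in every class were cell cycle, imprinted and fetal growth, antigen presentation, circadian clock, glucocorticoid and thyroid hormone response, and immediate early and dissociation stress. Those tested in chosen classes were osmolyte and tonicity response, collecting duct water and sodium transport, intercalated acid-base transport, thick limb transport, inner medulla handling of urea, water and chloride, proximal transport, fatty acid oxidation and gluconeogenesis, vasa recta and vascular specialisation, stromal progenitor, extracellular matrix, and injury. Male-biased and female-biased proximal genes and X- and Y-linked genes served to divide and compare nuclei by sex. Results for 2 single list members are not reported here; list counts include them.

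Free RNA was described from droplets beyond rank 20000 with at least 100 UMIs: 63092, 60537, 60603, 57355 and 61469 droplets at P0, P7, P14, P21 and 6 weeks. Their medians of 550, 638, 621, 579 and 479 UMIs leave room for fragments of nuclei among them. The share of a class at this profile was estimated from markers of other cell types, as the lowest ratio over marker sets; the lowest was chosen after the medians had been seen, so it is a lower estimate. Subtraction removed that share of the profile from the class sums.

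Alternatives covered depth limits, doublet removal, a clustering resolution of 1 in place of 2, each library clustered alone, nuclei without proximal tubule as denominator, age as rank, DESeq2, RLE scaling, no expression filter, thinned counts and each library left out. Added after the files had been seen were a depth limit of 1000 UMIs alone, one of 4000 UMIs, lenient naming, gene tests on subtracted counts, cycling at 1 or 3 UMIs, and share and cycling trends without P2 (exact over 120 orders). Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9. Gene positions come from GENCODE on GRCm38.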

Results

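The series measured RNA in single nuclei of mouse kidney at 6 postnatal ages: the day of birth (P0), P2, P7, P14, P21 and 6 weeks. Each age was 1 library, made from the kidneys of 4 wild-type mice, 2 male and 2 female, after part of the cortex had been removed by hand to enrich the medulla. Because every age is 1 library, no difference between 2 ages was tested and no p-value was made from nuclei; only trends over the 6 libraries were tested, against the logarithm of age. The deposited UMI counts summed to 86219387 at P0, 70559806 at P2, 107213421 at P7, 89519357 at P14, 87377013 at P21 and 94330527 at 6 weeks. Filtering kept 5807, 7707, 7464, 6722, 5541 and 7873 nuclei in that order, with median depths of 4488, 5637, 4960, 3967, 4582 and 4773 UMIs. Intervals given here are 95% intervals that cover counting error only, exact binomial (Clopper-Pearson) for shares and exact Poisson for UMI counts scaled to the class total (CPM). The P2 library differed from the others in its file header and held no empty droplets, so values that need empty droplets exist for 5 libraries only, and trends are also given without P2.

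The question behind the first comparison was how the cellular make-up of the kidney shifted from birth to young adulthood. Nuclei of the proximal tubule, the segment that reclaims most filtered solutes, rose from 8.23% (7.54 to 8.97%) at P0 to 42.7% (41.6 to 43.8%) at 6 weeks, through 14.8%, 30.9%, 36.5% and 32.1% at the ages between. The thick ascending limb, which reabsorbs salt without water, rose from 2.91% (2.49 to 3.38%) to 18.5% (17.6 to 19.3%). The distal convoluted and connecting tubule rose from 1.10% (0.850 to 1.41%) to 6.10% (5.58 to 6.65%), and the acid-base regulating intercalated cells from 0.551% (0.377 to 0.777%) to 2.74% (2.39 to 3.13%). Urothelium, the lining of the renal pelvis, rose from 0.861% (0.640 to 1.13%) to 2.57% (2.23 to 2.94%). Podocytes, the filtering cells of the glomerulus, fell from 4.68% (4.15 to 5.26%) to 0.457% (0.321 to 0.632%).

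Each of these 6 trends passed an exact two-sided permutation test over the 720 orders of the ages after Benjamini-Hochberg adjustment over 15 classes. Pearson's r was 0.967 for the proximal tubule (exact permutation p = 0.00417, adjusted p = 0.0208; Spearman's rho 0.943, exact p = 0.0167, adjusted p = 0.0417). It was 0.930 for the thick ascending limb (exact permutation p = 0.00972, adjusted p = 0.0292; rho 1.00, exact p = 0.00278, adjusted p = 0.0139). It was 0.948 for the distal convoluted and connecting tubule (exact permutation p = 0.00556, adjusted p = 0.0208) and 0.965 for intercalated cells (exact permutation p = 0.00417, adjusted p = 0.0208), both with rho 1.00 (exact p = 0.00278, adjusted p = 0.0139). It was 0.916 for urothelium (exact permutation p = 0.0125, adjusted p = 0.0312; rho 0.943, exact p = 0.0167, adjusted p = 0.0417) and -0.952 for podocytes (exact permutation p = 0.00278, adjusted p = 0.0208; rho -0.943, exact p = 0.0167, adjusted p = 0.0417). Without P0 and 6 weeks, the ages farthest from the median, r was 0.890, 0.942, 0.961, 0.924, 0.831 and -0.993 in the order of these classes. Over the 5 libraries without P2, r in the same order was 0.968, 0.926, 0.945, 0.961, 0.927 and -0.958 (exact permutation p over 120 orders 0.025, 0.00833, 0.00833, 0.00833, 0.0583 and 0.0167). The adjusted exact p was 0.0417 for the thick ascending limb, the distal convoluted and connecting tubule and intercalated cells, while proximal tubule (0.075), urothelium (0.125) and podocytes (0.0625) missed the threshold. By rho, all 6 missed the threshold at 4000 UMIs (adjusted exact permutation p = 0.0625 or more), and proximal tubule (0.143), podocytes (0.143), the thick ascending limb (0.0833) and urothelium (0.186) missed it with each library clustered alone. By rho none of the 6 passed without P2, with an adjusted exact p of 0.0833 where rho was 1.00 and 0.156 where it was 0.9 or -0.9. The urothelium trend missed the threshold with age as a rank (r = 0.881, adjusted exact permutation p = 0.0536), with each library clustered alone (r = 0.715, adjusted p = 0.192) and at a minimum of 4000 UMIs (r = 0.838, adjusted p = 0.0896), and the thick ascending limb trend missed it at 4000 UMIs (r = 0.795, adjusted p = 0.0896). All shares depend on how much cortex was removed at each age, and clusters left out of every class held, from P0 to 6 weeks, 8.56%, 13.8%, 12.1%, 13.7%, 20.3% and 12.5% of nuclei as mixed and 22.1%, 9.33%, 5.96%, 5.44%, 2.58% and 1.71% as unnamed.

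The cells that build new nephrons were seen mostly at the youngest ages. Nephron progenitors, named by genes such as Six2 and Cited1, were 18.1% (17.1 to 19.1%, 1052 nuclei) at P0 and 7.81% (7.22 to 8.43%, 602 nuclei) at P2. None was found at P7, P14, P21 or 6 weeks, where a count of 0 allows up to 0.0402%, 0.0446%, 0.0541% and 0.0381% (3 counts of the nuclei). The ureteric tip, which signals to the progenitors, was 4.25% at P0, 2.44% at P2 and 0% from P7 on, and early nephron stages were 3.19%, 5.72% and 0.0402% (3 nuclei) at P0, P2 and P7, then 0%, with the same upper bounds for each 0. These zeros depend on the depth limit. With 1000 UMIs alone, the ureteric tip had 65 nuclei at P7 (0.588%), 57 at P14 and 1 at P21. Nephron progenitors then had 1 at P7, and early nephron stages had 60, 19, 8 and 15 from P7 to 6 weeks (0.543% at P7 and 0.151% at 6 weeks). Stromal fibroblasts were 13.3%, 24.8%, 20.3%, 12.1%, 3.66% and 0.686% of nuclei from P0 to 6 weeks. These classes did not pass the trend test: adjusted exact permutation p was 0.0625 for nephron progenitors (r = -0.905, unadjusted p = 0.0333) and for the ureteric tip (r = -0.918, unadjusted p = 0.0333), 0.0694 for early nephron stages (r = -0.753, unadjusted p = 0.0417) and 0.171 for stroma (r = -0.667, unadjusted p = 0.149). For stroma this depends on the naming and on the nuclei kept. The adjusted exact p was 0.0156 with lenient naming (r = -0.961), which puts 160 nuclei in the class at 6 weeks against 54, 0.0238 at a clustering resolution of 1 and 0.0268 without doublet removal. Leaving out P0 and 6 weeks gave r of -0.878, -0.878, -0.881 and -0.947 in that order, and rho was -0.845, -0.845, -0.880 and -0.829 (exact permutation p = 0.0667, 0.0667, 0.05 and 0.0583; adjusted p = 0.0909 for all of these rho values). With 4 libraries at 0, nephron progenitors and the ureteric tip reached the smallest exact p their ties allow, 0.0333 for r and 0.0667 for rho. For rho the test could therefore not have passed there, and for r it could pass only if most other classes passed too. Without P2, r was -0.906, -0.906, -0.909 and -0.608 (adjusted exact permutation p = 0.273, 0.273, 0.125 and 0.317).

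The remaining classes also missed the threshold. Endothelium was 5.34% at P0, 7.53% at P14 and 2.98% at 6 weeks (r = -0.312, exact permutation p = 0.561, adjusted p = 0.561; rho -0.200, p = 0.714, adjusted p = 0.714; r = -0.0252 without P0 and 6 weeks), and its r was 0.939 with 1000 UMIs as the sole depth limit. Collecting duct principal cells, which reabsorb water under vasopressin, were 3.17%, 1.54% and 4.94% at P0, P7 and 6 weeks (r = 0.430, exact permutation p = 0.385, adjusted p = 0.412; rho 0.486, p = 0.356, adjusted p = 0.381; r = 0.444 without the end ages). The thin limb was 1.29% at P0 and 3.67% at 6 weeks (r = 0.805, exact permutation p = 0.0653, adjusted p = 0.0890; rho 0.6, p = 0.242, adjusted p = 0.279; 0.792 without the end ages). Immune nuclei were 1.33% and 0.292% (r = -0.818, exact permutation p = 0.0528, adjusted p = 0.0792; rho -0.829, p = 0.0583, adjusted p = 0.0909; -0.762), and mural, mesangial and renin nuclei 1.07% and 0.254% at the same ages (r = -0.701, exact permutation p = 0.129, adjusted p = 0.161; rho -0.6, p = 0.242, adjusted p = 0.279; -0.606). Without P2, r was -0.277, 0.389, 0.787, -0.797 and -0.650 in the order of this paragraph (adjusted exact permutation p = 0.625, 0.580, 0.264, 0.141 and 0.292). By rho, principal cells passed at a clustering resolution of 1, without doublet removal and with 1000 UMIs alone (adjusted exact permutation p = 0.0208, 0.0312 and 0.0208).

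The next comparison asked when nuclei carried transcripts of the cell cycle. After every nucleus had been thinned to 2000 UMIs, nuclei with at least 2 UMIs of 24 cell cycle genes, among them Mki67 and Top2a, were 29.6% (28.4 to 30.8%) at P0, 43.1% (41.98 to 44.2%) at P2, 24.9% at P7, 24.0% at P14, 4.04% (3.54 to 4.60%) at P21 and 5.55% (5.06 to 6.08%) at 6 weeks. Early nephron stages had the highest shares, 84.3% at P0 and 92.3% at P2, and nephron progenitors had 42.2% and 63.0%. Endothelium went from 25.2% at P0 and 56.4% at P2 to 9.79% at 6 weeks, and proximal tubule nuclei from 24.2% at P14 to 2.87% at P21. Immune nuclei were at 38.96% (28.0 to 50.8%) at P0 and 30.4% (13.2 to 52.9%) at 6 weeks. Podocytes, which leave the cell cycle as they mature, had 14.3%, 20.9%, 8.08% and 13.2% from P0 to P14, then 0% at P21 (0 to 14.8%, 23 nuclei) and 0% at 6 weeks (0 to 9.74%, 36 nuclei). The unthinned shares of all nuclei were 55.2%, 75.6%, 50.8%, 42.6%, 16.5% and 19.7%. The fall over the 6 libraries did not pass by Pearson's r (r = -0.789, exact permutation p = 0.0639), while rho was -0.886 (exact permutation p = 0.0333) and r was -0.935 without P0 and 6 weeks; this was 1 relation, so no adjustment applied. Without P2, r was -0.802 (exact permutation p = 0.075) and rho -0.9 (exact p = 0.0833). Free RNA alone, at the highest share of any class by the lowest estimate, would put 6.33%, 4.73%, 10.98%, 0.363% and 0.238% of nuclei over the limit of 2 UMIs at P0, P7, P14, P21 and 6 weeks, and 42.2%, 29.8%, 34.7%, 1.08% and 1.17% by the median estimate. These values apply the share of 1 class to all nuclei. In early nephron stages at P0 free RNA could not form the whole share, which lay above the 60.8% that nuclei of free RNA alone would give. For all nuclei at P0, P7 and P14 the median estimate lay above the observed shares, so free RNA as their source was not excluded. At P21 and 6 weeks the observed shares lay above both estimates, but below the 5.424% and 5.655% that nuclei of free RNA alone would give. P2 has no empty droplets to compute such values from. No nucleus was left out by thinning.

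**Figure D1:**
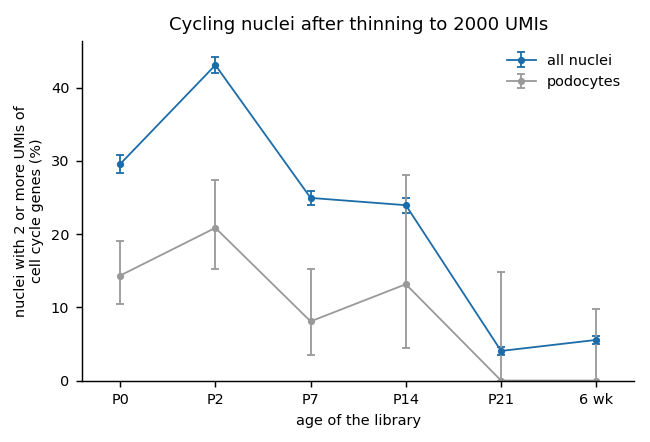
Share of nuclei (%) with at least 2 UMIs of cell cycle genes after thinning to 2000 UMIs, by age, for all nuclei and for podocytes with exact binomial 95% intervals; all nuclei peak at 43.1% at P2 and reach 4.04% at P21.

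The main comparison asked which genes changed with age in the summed RNA of each cell class. Such sums cannot tell change within cells from a changed mix of cells in the class. That mix may also depend on how much cortex was removed at each age. In 9 classes with at least 30 nuclei in every library, UMIs were summed per class and library, and edgeR's quasi-likelihood test was applied to the slope over log age, with Benjamini-Hochberg adjustment at 0.05 and 4 residual degrees of freedom. Changes below are fitted log2 changes from day 0 to day 42 over n = 6 libraries. The standard error (SE) beside a change is its size divided by the square root of edgeR's F statistic. Genes passed the test in every class: 961 in endothelium, 925 in stroma, 800 in principal cells, 640 in proximal tubule, 437 in the distal convoluted and connecting tubule, 427 in the thick ascending limb, 401 in intercalated cells, 254 in urothelium and 93 in the thin limb. Most of them, 1776 genes, passed in 1 class alone, and 7 passed in all 9: Kap, Umod, Cryab and Chdh rose, and Mest, Peg3 and Igf2bp2 fell. Free RNA was present in every class: the share of UMIs at the empty-droplet profile lay between 8.62% and 30.7% by the lowest estimate over marker sets, and between 18.6% and 70.1% by the median estimate. Of 258 gene and class pairs named by the fixed rule, 34 had a class level no more than 2 times what that share alone would give, and 224 lay above it. Over all calls the share at or under 2 times was 23.9%. These are minimum counts, since the lowest estimate over marker sets was used. At the median estimate they were 63 of 258 named pairs and 35.9% of all calls. At the lowest estimate it was, among genes that fell, 46.7% in the distal convoluted and connecting tubule, 41.7% in the thick ascending limb and 39.8% in proximal tubule, and among genes that rose it was highest in endothelium (37.4%). Subtracting the empty-droplet profile, which leaves 5 libraries, kept 48 of 211 named pairs past the test, and leaving out 1 library kept 199 of 239 without P0, 103 of 239 without P2, 215 of 257 without P7, 190 of 257 without P14, 141 of 242 without P21 and 93 of 242 without 6 weeks. The subtracted fit lacks P2. Its counts, here and below, therefore compare with those without P2 and not with the 6-library counts.

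Of the tested lists, the imprinted and fetal growth list had the most calls. It holds genes active before birth. Some of them drive growth and others, such as Grb10, restrain it. Its members fell in all 9 classes, 92 calls in total and no call upward: 13 of 15 tested in principal cells, 12 of 14 in the distal convoluted and connecting tubule, 14 of 17 in endothelium, 10 of 14 in intercalated cells, 12 of 17 in proximal tubule, 11 of 18 in stroma, 7 of 17 in the thick ascending limb, 4 of 15 in the thin limb and 9 of 17 in urothelium. Adjusted over the list alone, the counts were 13, 13, 16, 10, 14, 16, 13, 12 and 13 in that order. Peg3, an imprinted zinc finger gene, fell in principal cells from 1705 CPM at P0 to 135 at P2 and 19.03 at 6 weeks (log2 change -6.30 ± 0.56, SE, edgeR adjusted p = 0.00127). Meg3, a long noncoding RNA expressed from the maternal chromosome, fell from 176 to 1.19 CPM in the same cells (-7.00 ± 0.50, edgeR adjusted p = 0.000772). In endothelium, Mest fell from 521 to 11.7 CPM (-5.20 ± 0.75, edgeR adjusted p = 0.00718) and Igf2bp1, a fetal RNA-binding protein, from 56.6 to 0 CPM (-5.54 ± 0.63, edgeR adjusted p = 0.00403). The set test (camera) passed in each class with its preset correlation and in none with an estimated correlation: adjusted p = 0.226 with an estimated correlation in principal cells, the distal convoluted and connecting tubule, endothelium and the thin limb, 0.272 in intercalated cells, proximal tubule, stroma and urothelium, and 0.320 in the thick ascending limb. Over all lists and classes, 48 of 70 set tests passed with the preset correlation and 0 with an estimated correlation. Without P2, P21 or 6 weeks the 92 calls became 47, 52 and 40. Of the 92, 25 were at no more than 2 times the level free RNA alone would give at the lowest estimate. At the median estimate 50 were. Genes outside the lists also fell in many classes. Aldh1a2, Cacna2d1, Eya1, Nell1, Rps4x and Wt1 fell in 8, and Asic2, Gm26917, Hif3a, Hist1h2ap, Npm1, Rpl13, Rpl15, Rpl17, Rpl23, Rpl32, Rpl36a, Rpl39, Rpl4, Rps18, Rps23, Rps27a and Tpt1 in 7. Eya1, Nell1, Wt1 and Asic2 are leading genes of nephron progenitor clusters, and that class was found at P0 and P2 alone with the filters used. No list of ribosomal or nephron progenitor genes was tested. Malat1, a noncoding RNA kept in the nucleus, was at 55482 CPM of all nuclei at P0 and 139595 CPM at 6 weeks. No adjustment was made for the balance of nuclear and cytoplasmic RNA.

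In the thick ascending limb, 228 genes rose and 199 fell. Egf, which encodes the epidermal growth factor precursor shed into urine, rose from 25.4 CPM (15.5 to 39.2) at P0 through 166, 494, 1777 and 5180 to 8881 CPM (8802 to 8961) at 6 weeks (log2 change 8.74 ± 0.55, SE, edgeR adjusted p = 0.00356). It lies on chromosome 3 at 129677565 to 129755316 (GRCm38, minus strand, protein coding). Umod, the gene of uromodulin, the most abundant urinary protein, rose from 105 to 1996 CPM (4.09 ± 0.55, edgeR adjusted p = 0.0138). Egf passed upward in 8 of the 9 tested classes and Umod in all 9. Slc12a1, the salt cotransporter that defines the segment, was at 16200 CPM at P0 and 16210 CPM at 6 weeks and did not pass. Of 20 tested members of the thick limb transport list, Egf and Umod rose and 1 fell, the same counts adjusted over the list alone. Neither Egf nor Umod encodes a transporter. The list's set test did not pass (camera adjusted p = 0.677 with an estimated correlation). Afp, a fetal serum protein gene, fell from 54.5 to 1.11 CPM. Cluster 42 held the class at P0, mostly cluster 6 from P2 to P14, and clusters 2 and 14 at P21 and 6 weeks. The 427 calls became 671 without P0, 20 without P2, 237 without P7, 129 without P21 and 36 without 6 weeks, and 9 after subtraction of the empty-droplet profile. Egf passed edgeR's test without each library in turn. Umod missed it without P2 (adjusted p = 0.0654) or 6 weeks (0.0657), Afp without P2 (0.0531), and the 3 list calls became 1 without P2 and 1 without 6 weeks.

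In the distal convoluted and connecting tubule, 223 genes rose and 214 fell. Egf rose there too, from 15.6 to 3864 CPM (log2 change 11.42 ± 1.16, SE, edgeR adjusted p = 0.00182). Uroc1, an enzyme of histidine breakdown, rose from 6.25 to 136 CPM (6.52 ± 0.79, edgeR adjusted p = 0.00247). Lgr5, a stem-cell marker in several epithelia, fell from 93.7 CPM at P0 to 1.76 CPM at 6 weeks (-6.91 ± 0.96, edgeR adjusted p = 0.00482), and Sec14l1 fell from 971 to 70.5 CPM (-3.34 ± 0.33, edgeR adjusted p = 0.00182). These 4 genes passed without each library in turn. Cluster 34 held most of the class up to P14 and clusters 44, 59 and 71 most of it later. The 437 calls became 699 without P0, 141 without P2, 197 without P21 and 113 without 6 weeks, and 68 after subtraction of the empty-droplet profile.

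In collecting duct principal cells, 396 genes rose and 404 fell. Hsd11b2, the enzyme that inactivates glucocorticoids and so keeps the mineralocorticoid receptor for aldosterone, rose from 9.33 to 115 CPM (log2 change 4.05 ± 0.53, SE, edgeR adjusted p = 0.00584). Nr3c2, the mineralocorticoid receptor itself, rose from 227 to 1097 CPM (2.68 ± 0.35, edgeR adjusted p = 0.00548). Kcnj1, the secretory potassium channel, rose from 2.80 to 53.5 CPM (4.59 ± 0.65, edgeR adjusted p = 0.00740), while Aqp2, the vasopressin-regulated water channel, was at 274 CPM at P0, 124 at P2, 598 at P21 and 1140 at 6 weeks and did not pass. Hif3a, a member of the hypoxia-inducible factor family, fell from 291 CPM (260 to 325) at P0 through 58.9, 20.7, 13.8 and 0.826 to 0.595 CPM (0.0150 to 3.31) at 6 weeks (-7.57 ± 0.60, edgeR adjusted p = 0.000907). It lies on chromosome 7 at 17031507 to 17062427 (minus strand, protein coding, GRCm38). Of 19 tested members of the water and sodium transport list, 5 rose and 1 fell. Adjusted over the list alone, 9 rose and 1 fell (camera adjusted p = 8.65e-05 with the preset correlation and 0.337 with an estimated correlation). Those that rose included Nr3c2 and Hsd11b2, a receptor and an enzyme and not transporters. Cluster 26 held nearly all of the class up to P7 and 74.6% at P14, where cluster 60 held 23.8%. Clusters 47 and 60 held nearly all of it at P21 and 6 weeks. Hsd11b2, Nr3c2, Kcnj1 and Hif3a passed without each library in turn. The 800 calls became 300 without P2, 322 without P21 and 184 without 6 weeks, the 6 list calls 11 without P0, 3 without P21 and 3 without 6 weeks, and 130 genes passed after subtraction of the empty-droplet profile.

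In intercalated cells, 168 genes rose and 233 fell. Aqp6, an anion-permeable water channel of these cells, rose from 28.9 to 279 CPM (log2 change 2.81 ± 0.35, SE, edgeR adjusted p = 0.00304). Slc26a4, the apical bicarbonate exchanger pendrin, rose from 795 to 3018 CPM (1.72 ± 0.32, edgeR adjusted p = 0.0153), and Slc4a1, the basolateral exchanger that releases bicarbonate to blood, from 14.5 to 140 CPM (3.16 ± 0.66, edgeR adjusted p = 0.0243). Hmga2, a chromatin protein of fetal tissues, fell from 323 to 5.32 CPM (-5.67 ± 0.60, edgeR adjusted p = 0.00122). Of 18 tested acid-base transport genes 5 rose and none fell. Adjusted over the list alone, 8 rose (camera adjusted p = 0.000362 with the preset correlation and 0.337 with an estimated correlation). The class was cluster 17 at every age and held 32 nuclei at P0. Aqp6 and Hmga2 passed edgeR's test without each library in turn. Slc26a4 missed without 6 weeks (adjusted p = 0.113) and Slc4a1 without P2 (0.0990) or 6 weeks (0.0659). The 401 calls became 104 without P2, 153 without P21 and 107 without 6 weeks, the 5 list calls 2, 3 and 1, and 41 genes passed after subtraction of the empty-droplet profile.

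In the thin limb, the segment of the inner medulla that is permeable to water or to chloride and urea, 58 genes rose and 35 fell. Atp10b, a phospholipid flippase gene, rose from 2.35 to 508 CPM (log2 change 8.97 ± 0.67, SE, edgeR adjusted p = 0.00305). Hif3a fell from 319 to 3.41 CPM (-6.69 ± 0.43, edgeR adjusted p = 0.00170). Bsnd, a subunit of the chloride channels of this region, rose from 4.69 to 130 CPM (4.36 ± 0.43, edgeR adjusted p = 0.0114). Of 13 tested genes for urea, water and chloride handling 4 rose. Adjusted over the list alone, 6 rose and 1 fell (camera adjusted p = 0.000118 with the preset correlation and 0.337 with an estimated correlation). Slc14a2, the urea transporter gene, was at 310 CPM at P0, 705 at P21 and 367 at 6 weeks, and Aqp1, the water channel, at 68.0 and 214 CPM at P0 and 6 weeks; neither passed. Cluster 27 held 66.3% to 78.6% of the class up to P14, and cluster 51 held 20.8% to 31.3% at these ages. Clusters 51 and 55 held most of it later. The 93 calls became 703 without P0, 5 without P2, 12 without P14, 18 without P21 and 3 without 6 weeks, and 2 after subtraction of the empty-droplet profile. Atp10b and Hif3a passed edgeR's test without each library in turn. Bsnd missed without 6 weeks (adjusted p = 0.129), and the 4 list calls became 8, 1, 2, 2, 1 and 0 without P0, P2, P7, P14, P21 and 6 weeks.

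Some genes of the response to high salt and urea, conditions that the medulla meets when urine is concentrated, rose with age. With adjustment over all genes they were a minority of the list in each class. Adjusted over the list alone, they were 8 of 15 in endothelium and 9 of 15 in stroma. The list's set test passed in all 5 classes tested with the preset correlation (camera adjusted p = 0.000454 to 0.0144). With an estimated correlation it passed in none (camera adjusted p = 0.337 in each). The osmolyte and tonicity list had 5 of 15 tested members up in principal cells, 6 of 15 up and 1 down in endothelium, 4 of 15 up in stroma, 3 of 15 up in the thin limb and 1 of 16 up in the thick ascending limb, where that call, Cryab, lay at 1.01 times the level free RNA would give. Adjusted over the list alone, 7, 8, 9, 5 and 5 rose and 1, 1, 1, 0 and 0 fell in that order. Cryab, a small heat shock protein of medullary cells, rose in principal cells from 4.67 to 195 CPM (log2 change 5.65 ± 0.70, SE, edgeR adjusted p = 0.00484), and Hspa1b, an inducible heat shock protein, from 5.599 to 82.1 CPM there (4.42 ± 0.45, edgeR adjusted p = 0.00239). Slc5a3, the carrier of the osmolyte myo-inositol, rose in endothelium from 20.2 to 202 CPM (4.36 ± 0.69, edgeR adjusted p = 0.00885). Cryab, Hspa1b and Slc5a3 passed without each library in turn in the classes named. By the lowest estimate, Slc5a3 in endothelium lay at 1.97 times the level free RNA would give, and Cryab in principal cells at 3.48 times. The median estimate of the free RNA share in principal cells was higher, 34.1% against 14.3% at P21 and 23.4% against 9.23% at 6 weeks. Cryab rose in all 9 classes, so its rise was not particular to the classes of this list. The 20 calls became 32 without P0, 10 without P2, 12 without P21 and 11 without 6 weeks. Of the 20, 4 were at no more than 2 times the level free RNA alone would give (9 at the median estimate). Hspa1a and Hspa1b are also on the immediate early and dissociation stress list, and they made 2 of the 5 calls in principal cells, 1 of the 6 upward calls in endothelium and 2 of the 4 in stroma.

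In endothelium, 615 genes rose and 346 fell. Genes that present antigen to T cells rose: 8 of 13 tested in this class, and 13 of 13 adjusted over the list alone. Camera's adjusted p was 5.03e-08 with the preset correlation and 0.337 with an estimated correlation. Nlrc5, the transactivator of MHC class I genes, rose from 3.23 to 89.8 CPM (log2 change 6.28 ± 0.87, SE, edgeR adjusted p = 0.00674), and the class I gene H2-K1 from 12.1 to 238 CPM (5.21 ± 0.84, edgeR adjusted p = 0.00900). The interferon-inducible genes Ifi213 and Phf11d rose from 0.808 to 70.3 CPM (9.44 ± 0.93, edgeR adjusted p = 0.00342) and from 0.808 to 75.5 CPM (6.87 ± 0.67, edgeR adjusted p = 0.00342). Col13a1, a transmembrane collagen gene, fell from 346 to 11.7 CPM (-3.85 ± 0.46, edgeR adjusted p = 0.00413). Of 16 tested vasa recta and vascular genes 3 rose, Esm1, Plvap and Igfbp5, also adjusted over the list alone (adjusted p = 0.556 with an estimated correlation); Plvap, the gene of fenestral diaphragms, went from 121 to 427 CPM. In the other classes antigen presentation genes rose in smaller numbers: 3 of 14 in stroma, 3 of 10 in urothelium, 2 of 4 in principal cells, 2 of 8 in the thick ascending limb, 1 of 5 in the distal convoluted and connecting tubule and 1 of 4 in intercalated cells. Some calls were at no more than 2 times the level free RNA alone would give at the lowest estimate. They were all 3 in stroma, the single calls in intercalated cells and in the distal convoluted and connecting tubule, and Cd74 in the thick ascending limb.

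The antigen presentation counts adjusted over the list alone were 4, 7, 4, 3, 2 and 2 in the last 6 classes, with adjusted p = 0.337 with an estimated correlation in each except the distal convoluted and connecting tubule (0.321). With edgeR, 0 of 14 in proximal tubule and 0 of 4 in the thin limb passed over all genes; at an unadjusted p under 0.05 the counts were 4 and 4 upward, and with DESeq2 they were 1 and 1. Adjusted over the list alone, 0 and 4 rose (adjusted p = 0.337 and 0.321 with an estimated correlation). In all, 20 calls became 5 without P2, 13 without P7, 5 without P21 and 2 without 6 weeks. Of the 20, 9 were at no more than 2 times the level free RNA alone would give at the median estimate. Cluster 4 held most of endothelium up to P14, with smaller parts in clusters 21, 56 and 75. Endothelium was mostly cluster 21 at P21 and 6 weeks. Its 961 calls became 1824 without P0, 354 without P2, 490 without P21 and 358 without 6 weeks, and 61 after subtraction of the empty-droplet profile. Nlrc5, Ifi213, Phf11d, Col13a1 and Esm1 passed edgeR's test without each library in turn. H2-K1 missed without 6 weeks (adjusted p = 0.0640), Plvap without P2 (0.0774) or 6 weeks (0.118), and Igfbp5 without P2, P7, P14, P21 or 6 weeks (0.104, 0.0676, 0.0626, 0.0844 and 0.109). The 3 vasa recta calls became 7 without P0 and 1 without P2.

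In stroma, 451 genes rose and 474 fell. Nrxn3, a cell adhesion gene best known from synapses, fell from 5359 CPM (5288 to 5430) at P0 through 3221, 546, 91.6 and 28.3 to 32.2 CPM (11.8 to 70.1) at 6 weeks (log2 change -9.12 ± 1.06, SE, edgeR adjusted p = 0.00777). It lies on chromosome 12 at 88722876 to 90334935 (GRCm38, plus strand, protein coding). Col23a1, a transmembrane collagen gene, fell from 561 to 5.37 CPM (-6.05 ± 0.56, edgeR adjusted p = 0.00550), and Zfp536, a neural zinc finger gene, from 736 to 10.7 CPM (-5.84 ± 0.66, edgeR adjusted p = 0.00777). Htra1, a secreted protease gene, rose from 1.46 to 123 CPM (6.76 ± 0.57, edgeR adjusted p = 0.00545). Hsd11b1, which regenerates active glucocorticoid, went from 8.30 CPM at P0 and 34.7 at P14 to 679 at P21 and 483 at 6 weeks (7.50 ± 1.81, edgeR adjusted p = 0.0459). Cell cycle genes fell: 6 of 24 over all genes and 21 of 24 adjusted over the list alone (adjusted p = 0.337 with an estimated correlation), with Cdk1, the mitotic kinase, going from 40.5 to 0 CPM (-3.99 ± 0.80, edgeR adjusted p = 0.0287). The stroma sum at 6 weeks held 186339 UMIs, so this 0 leaves room for a low level. Of 14 stromal progenitor genes 2 fell, among them Sox11, which lay at 1.77 times the level free RNA alone would give. Adjusted over the list alone, 6 fell and 1 rose (adjusted p = 0.347 with an estimated correlation). Of 20 matrix genes Col6a3 rose and Fbn2 fell, and 2 rose and 3 fell adjusted over the list alone (adjusted p = 0.858 with an estimated correlation).

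The stroma class was held by different clusters as the mice aged: 9, 11 and 20 at P0, 7, 9 and 11 at P2, 7, 9 and 15 at P7, 7, 9 and 52 at P14, and 65 and 73 at P21 and 6 weeks, with 54 nuclei at 6 weeks. Its 925 calls became 168 without P2, 256 without P14, 455 without P21 and 223 without 6 weeks, and 14 after subtraction of the empty-droplet profile. Thinning the class to its smallest library, with 54 nuclei, left 0 genes past edgeR's test (288 at an unadjusted p under 0.05; DESeq2 was not run on thinned counts). Nrxn3, Col23a1, Zfp536 and Htra1 passed edgeR's test without each library in turn. Hsd11b1 missed without P2 (adjusted p = 0.133), P14 (0.0748) or 6 weeks (0.1204), and Cdk1 without P2 (0.0652), P14 (0.0845) or 6 weeks (0.0782). Sox11 missed without P14, P21 or 6 weeks (0.0985, 0.0777 and 0.0914). The 2 stromal progenitor calls became 6, 1, 3, 0, 0 and 0 and the 2 matrix calls 1, 0, 1, 0, 1 and 0 without P0, P2, P7, P14, P21 and 6 weeks; Col6a3 missed without P0, P2, P7, P14, P21 or 6 weeks (0.276, 0.0756, 0.0626, 0.0957, 0.0577 and 0.144) and Fbn2 without P2, P14 or 6 weeks (0.0767, 0.0776 and 0.0963).

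In proximal tubule, 313 genes rose and 327 fell. Cyp27b1, the kidney enzyme that activates vitamin D, fell from 479 CPM (455 to 505) at P0 to 27.4 at P2 and 5.74 CPM (4.78 to 6.84) at 6 weeks (log2 change -6.03 ± 0.80, SE, edgeR adjusted p = 0.0209). It lies on chromosome 10 at 127048250 to 127053006 (GRCm38, plus strand, protein coding). Kcnn1, a calcium-activated potassium channel gene, fell from 31.7 to 0.821 CPM (-5.37 ± 0.52, edgeR adjusted p = 0.00992). The vomeronasal receptor genes Vmn1r18 and Vmn1r20 rose from 1.34 to 233 CPM (9.29 ± 0.84, edgeR adjusted p = 0.00943) and from 0 to 77.3 CPM (9.98 ± 0.86, edgeR adjusted p = 0.00756); they belong to a family of near-identical copies, so reads may be divided between members. Slc34a1, the main phosphate carrier, was at 2977 and 4416 CPM at P0 and 6 weeks, and Slc5a2, the glucose carrier of the early segment, at 33.1 CPM at P0, 309 at P2 and 300.0 at 6 weeks; neither passed. With edgeR, 0 of 29 proximal transport genes passed over all genes, 11 rose and 1 fell at an unadjusted p under 0.05, and DESeq2 called 10 up, while 7 rose adjusted over the list alone (adjusted p = 0.337 with an estimated correlation). Those 7 became 2, 6, 0, 5, 5 and 1 without P0, P2, P7, P14, P21 and 6 weeks. Of 22 fatty acid oxidation and gluconeogenesis genes edgeR called 0, also adjusted over the list alone, 4 rose and 1 fell at an unadjusted p under 0.05, and DESeq2 called 1 up (adjusted p = 0.969 with an estimated correlation).

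Different clusters held the proximal tubule at different ages: 37 at P0, 1, 3 and 10 at P2, 1, 3 and 5 at P7 and P14, 23, 30 and 33 at P21, and 12, 13, 25, 32 and 36 at 6 weeks. Its 640 calls became 239 without P0, 63 without P2, 150 without P7, 326 without P14, 61 without P21 and 154 without 6 weeks, and 43 after subtraction of the empty-droplet profile; DESeq2 called 1988. Kcnn1, Vmn1r18 and Vmn1r20 passed edgeR's test without each library in turn, and Cyp27b1 missed without P0 (adjusted p = 0.0560) or P21 (0.0747). On simulated counts for 16040 genes of this class, edgeR's test recovered 0%, 20%, 76% and 88% of genes changed 2-, 4-, 8- and 16-fold. Most simulated changes of 4-fold or less therefore went undetected. The simulation changed 50 genes at each fold with 1 dispersion of 0.118 and gave 95 calls against 640 in the data. It does not give the share of real changes that was missed.

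In urothelium, 161 genes rose and 93 fell. Cp, the gene of the copper carrier ceruloplasmin, rose from 0 to 146 CPM (log2 change 8.07 ± 0.73, SE, edgeR adjusted p = 0.00374). Muc1, a mucin of the epithelial surface, rose from 1.81 to 86.2 CPM (6.72 ± 0.78, edgeR adjusted p = 0.00830), and H2-Q7, a class I gene, from 0 to 31.3 CPM (8.33 ± 1.26, edgeR adjusted p = 0.0153). Plag1, a fetal growth transcription factor, fell from 105 to 7.83 CPM (-3.70 ± 0.40, edgeR adjusted p = 0.00573). Clusters 43 and 48 held the class at all ages. The 254 calls became 45 without P2, 156 without P14, 64 without P21 and 137 without 6 weeks; after subtraction of the empty-droplet profile edgeR called 0 (1293 at an unadjusted p under 0.05; DESeq2 was not run on subtracted counts). Cp and Muc1 passed without each library in turn, as did H2-Q7 without each of the libraries that left it enough counts to be tested.

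**Figure D2:**
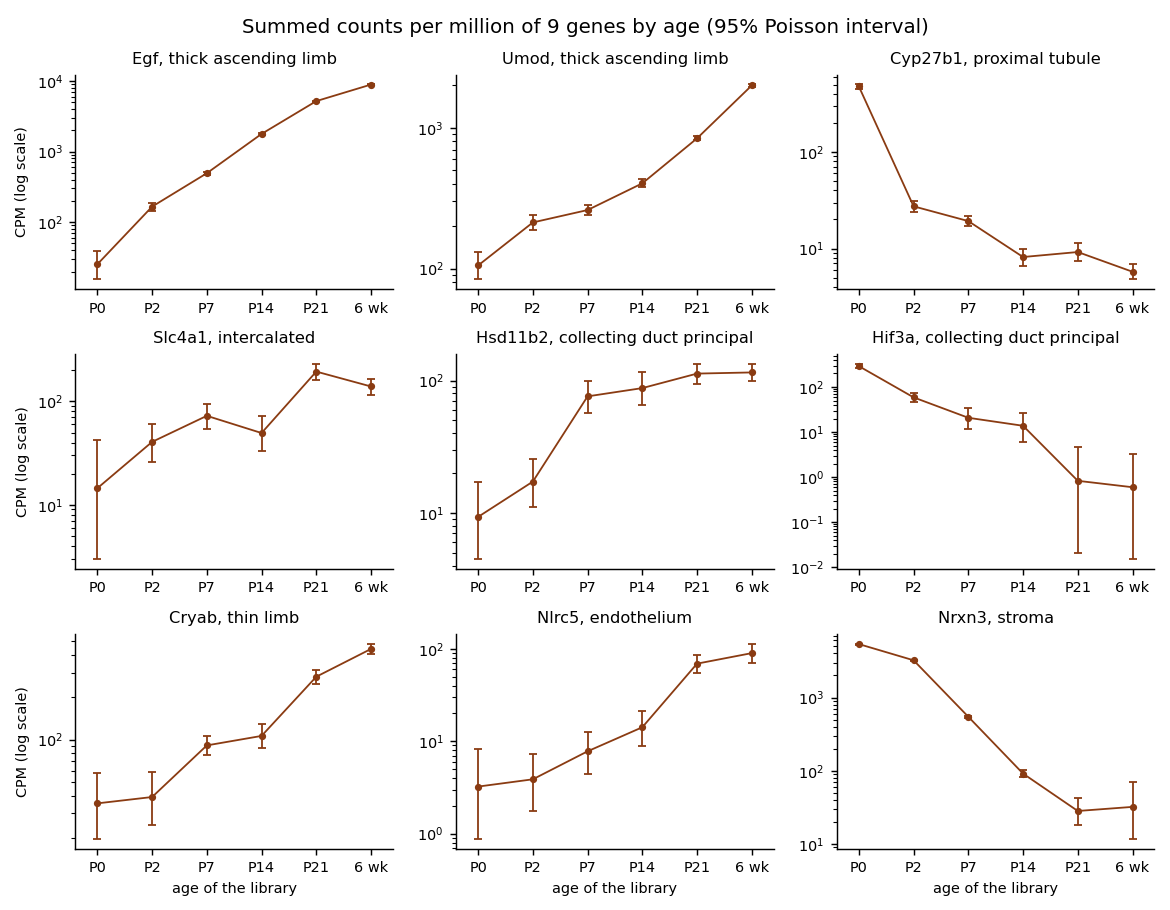
CPM (log axis) by age for 9 genes in the class named on each panel, 1 point per library with exact Poisson 95% intervals; Egf in the thick ascending limb goes from 25.4 to 8881 CPM, and Nrxn3 in stroma from 5359 to 32.2 CPM.

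Cell cycle genes fell, besides stroma, in the distal convoluted and connecting tubule (2 of 16, 4 adjusted over the list alone), principal cells (1 of 15, 1) and urothelium (1 of 19, 1) (adjusted p = 0.337, 0.387 and 0.339 with an estimated correlation). With edgeR, 0 cell cycle genes passed in endothelium, intercalated cells, proximal tubule, the thick ascending limb and the thin limb; 6, 7, 1, 5 and 2 fell at an unadjusted p under 0.05, DESeq2 called 5, 5, 1, 2 and 0 down, and 0, 7, 0, 0 and 0 fell adjusted over the list alone (adjusted p = 0.388, 0.353, 0.655, 0.388 and 0.438 with an estimated correlation). The 10 cell cycle calls became 55 without P0, 1 without P2, 6 without P7, 3 without P14, 5 without P21 (4 down and 1 up) and 0 without 6 weeks. Of the 10, 2 were at no more than 2 times the level free RNA alone would give at the median estimate.

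Circadian clock genes rose in endothelium (6 of 16), stroma (5 of 17), proximal tubule (3 of 19), intercalated cells (2 of 15), urothelium (1 of 15) and principal cells (1 of 15, with 1 more down). Adjusted over the list alone, 6, 9, 7, 4, 1 and 2 rose and 1, 0, 1, 2, 0 and 1 fell in that order. Dbp, a transcription factor driven by the clock, went from 0 to 37.3 CPM in intercalated cells (log2 change 7.03 ± 1.17, SE, edgeR adjusted p = 0.00957). The intercalated sum at P0 held 207530 UMIs, so this 0 leaves room for a low level. The adjusted p with an estimated correlation was 0.272 in stroma, 0.337 in endothelium, proximal tubule and urothelium, 0.383 in intercalated cells and 0.509 in principal cells. With edgeR, 0 of 14, 0 of 18 and 0 of 14 passed in the distal convoluted and connecting tubule, the thick ascending limb and the thin limb; at an unadjusted p under 0.05, 2, 7 and 5 rose and 2, 2 and 0 fell, DESeq2 called 0, 2 and 0 up and 1, 1 and 0 down, and adjusted over the list alone 2, 4 and 1 rose and 2, 1 and 0 fell (adjusted p = 0.869, 0.679 and 0.446 with an estimated correlation). The 19 calls became 37 without P0, 6 without P2, 6 without P21 and 1 without 6 weeks. Of the 19, 8 were at no more than 2 times the level free RNA alone would give at the median estimate. The time of day at which the mice were killed is not given.

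Of the glucocorticoid and thyroid hormone list, 15 calls were made. Thrb, a thyroid hormone receptor gene, rose in 8 classes, for example in endothelium from 35.6 to 254 CPM (log2 change 3.24 ± 0.32, SE, edgeR adjusted p = 0.00342), and Nr3c2 rose in principal cells, endothelium and urothelium. Nr3c1, the glucocorticoid receptor, fell in principal cells from 205 to 54.1 CPM (-1.81 ± 0.30, edgeR adjusted p = 0.0116; 0.0665 without 6 weeks). The counts by class were 2 up and 1 down of 14 in principal cells, 1 of 13 in the distal convoluted and connecting tubule, 2 of 14 in endothelium, 2 of 12 in intercalated cells, 1 of 15 in proximal tubule, 2 of 16 in stroma, 1 of 15 in the thick ascending limb, 1 down of 14 in the thin limb and 2 of 14 in urothelium. Adjusted over the list alone, 3, 2, 2, 5, 3, 4, 1, 3 and 5 rose and 1, 0, 0, 0, 0, 0, 1, 1 and 0 fell (adjusted p = 0.438, 0.743, 0.438, 0.337, 0.387, 0.339, 0.446, 0.523 and 0.351 with an estimated correlation). The 15 calls became 49 without P0, 6 without P2, 9 without P21 and 7 without 6 weeks. Of the 15, 3 were at no more than 2 times the level free RNA alone would give at the median estimate.

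Of the immediate early and dissociation stress list, 9 calls were made, all upward: 3 of 12 in principal cells, 2 of 14 in endothelium, 2 of 15 in stroma and 2 of 14 in urothelium. They came from the heat shock genes Hspa1a and Hspa1b and from Btg2, an antiproliferative gene. With edgeR 0 passed in the distal convoluted and connecting tubule, intercalated cells, proximal tubule, the thick ascending limb and the thin limb; 3, 2, 2, 5 and 4 rose at an unadjusted p under 0.05, and DESeq2 called 0, 0, 2, 2 and 1 up. Adjusted over the list alone, 5, 7, 5 and 3 rose in the first 4 classes and 2, 0, 2, 2 and 3 in the others. The adjusted p with an estimated correlation was 0.383, 0.320, 0.383 and 0.396 in the first 4 classes and 0.436, 0.337, 0.746, 0.509 and 0.337 in the others. The 9 calls became 23 without P0, 1 without P2, 3 without P21 and 3 without 6 weeks. Of the 9, 4 were at no more than 2 times the level free RNA alone would give at the median estimate. Of the injury list, Krt20, a keratin gene, fell in proximal tubule (1 of 10; 1 rose and 1 fell adjusted over the list alone) and Spp1, the gene of osteopontin, passed upward in the thick ascending limb (1 of 6; 1 rose and 2 fell adjusted over the list alone), where its fitted change became -0.10 after subtraction of the empty-droplet profile (adjusted p = 0.388 and 0.523 with an estimated correlation). These 2 calls became 3 without P0, 0 without P2, 0 without P7, 1 without P14, 0 without P21 and 0 without 6 weeks.

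Some genes stood apart at the ends of the series and so could not pass a straight-line test; they are given as values. Zbtb16, a zinc finger gene induced by glucocorticoids, was at 456 CPM (432 to 481) in proximal tubule at P0, 1.65 (0.904 to 2.77) at P2, 1.75 at P7, 2.06 at P14, 158 at P21 and 67.0 at 6 weeks. In stroma it was at 295, 3.19, 2.34, 18.2, 1217 and 1331 CPM, and over the 9 classes it lay between 119 and 605 CPM at P0. Fkbp5, a chaperone gene that responds to the same hormones, was at 386, 33.9, 22.8, 24.7, 329 and 542 CPM in proximal tubule. The median log2 ratio over classes of P0 over the mean of P2, P7 and P14 was 5.87 for Zbtb16, 2.62 for Fkbp5, 1.90 for Per1 and 1.35 for Sgk1, and that of P21 and 6 weeks over the same ages was 5.30, 2.20, 1.99 and 2.17. Zbtb16 lies on chromosome 9 at 48654297 to 48836222 (GRCm38, minus strand, protein coding). These genes belong to a fixed list and were picked from it after their values were seen. Of the 16 members, 10 had a median above 0 at P0, these 4 alone reached 1, and 13 had a median above 0 at P21 and 6 weeks; Pdk4 went the other way (-1.03 and -0.76).

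Kap, a gene of the proximal tubule that responds to androgen, passed the test upward in all 9 classes. In proximal tubule it went from 23.7 CPM at P0 to 1228 CPM at 6 weeks, and in the other 8 classes it reached 731 (urothelium) to 1272 CPM (stroma) at 6 weeks. The empty droplets held 70.6 CPM of Kap at P0 and 7002 CPM at 6 weeks. After subtraction of the empty-droplet profile, Kap at 6 weeks was at 650 CPM in proximal tubule, 319 in principal cells, 12.8 in the thick ascending limb and 0 in the other 6 classes. At P21 it was at 527 in proximal tubule, 232 in stroma and 174 in endothelium. In proximal tubule at 6 weeks, the subtracted share was 9.09%, the lowest over marker sets, while Kap stood at 17.5% of its empty-droplet level and the median share over marker sets was 18.6%. Kap lies on chromosome 6 at 133849851 to 133853762 (GRCm38, minus strand, protein coding).

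**Figure D3:**
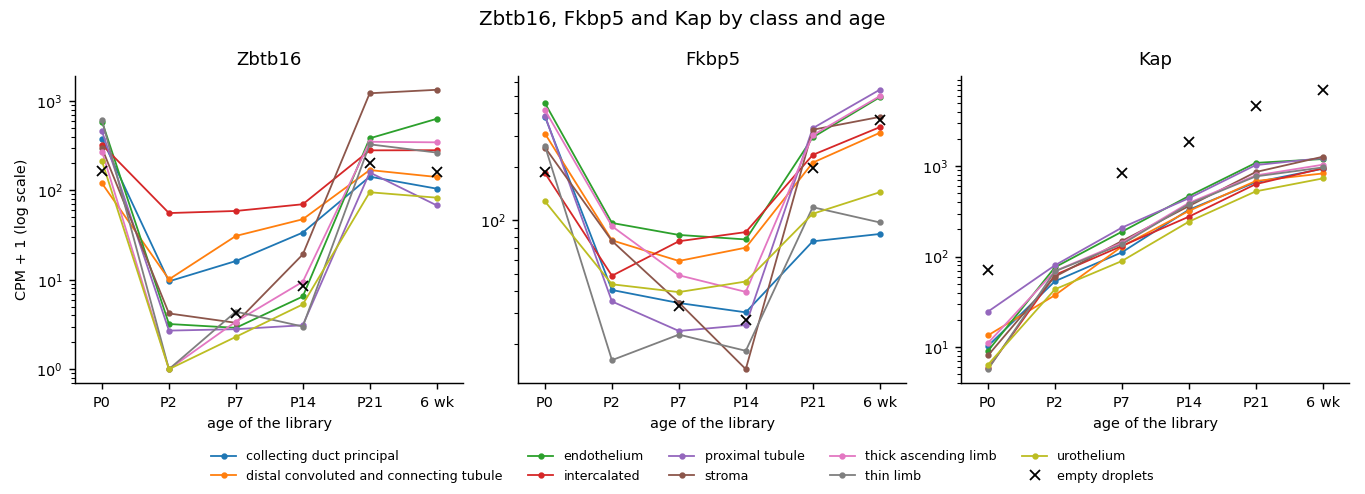
CPM plus 1 (log axis) of Zbtb16, Fkbp5 and Kap by age, 1 line per class, with crosses for the empty droplets of the 5 libraries that hold them; Zbtb16 in proximal tubule is at 456 CPM at P0 and 1.65 at P2, and Kap in empty droplets reaches 7002 CPM at 6 weeks.

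Each library mixes 2 male and 2 female mice, so proximal tubule nuclei were divided by their own transcripts into those with UMIs of Y-linked genes and no Xist, and those with Xist and no Y-linked UMIs. At 6 weeks this gave 1106 and 1298 nuclei, with 873 that held both and 81 that held neither. At the other ages the nuclei with Y-linked UMIs and those with Xist were 64 and 291 at P0, 333 and 495 at P2, 687 and 822 at P7, 388 and 1233 at P14, and 580 and 605 at P21. The split was uneven at P0 and P14. Slc7a13, an amino acid carrier of the late segment, was at 1117 CPM in nuclei with Y-linked UMIs and 63.2 CPM in those with Xist, and Cyp7b1, an oxysterol hydroxylase, at 598 and 30.2 CPM. Slc7a12, a related carrier, was at 22.5 and 1075 CPM, and Prlr, the prolactin receptor, at 44.3 and 612 CPM. Of 17 genes of the male-biased and female-biased lists that could be compared at 6 weeks, 16 differed in the direction of their list with intervals apart, and Slco1a4 differed the other way; the median log2 ratio in the direction of the list was 3.401. At P21 the same ratio had a median of 0.00 over 12 genes, of which 6 went in the direction of their list. Slc7a12 was then at 644 and 628 CPM, Prlr at 1077 and 954 CPM, and Slc7a13 at 135 and 93.4 CPM. At P0, P2, P7 and P14 the median lay between -0.08 and 0.04. Slc7a12 lies on chromosome 3 at 14480697 to 14505830 (plus strand) and Slc7a13 on chromosome 4 at 19818725 to 19842218 (plus strand, both GRCm38 and protein coding). The nuclei of 1 pool are not replicates, so no test was run.

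**Figure D4:**
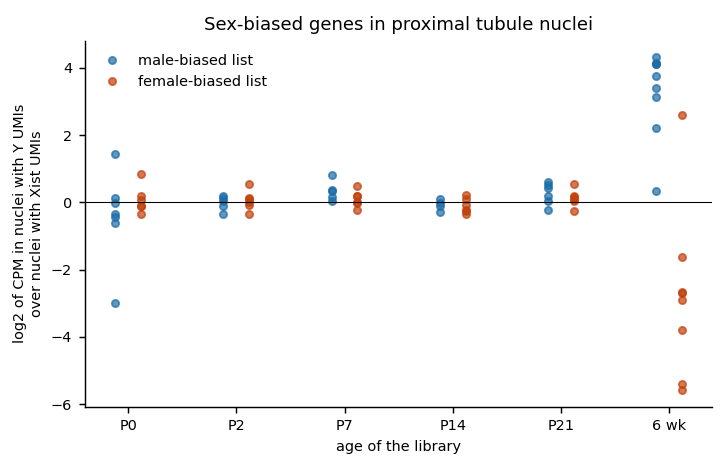
Log2 ratio of CPM in proximal tubule nuclei with Y-linked UMIs over those with Xist, 1 point per gene and age, for genes of the male-biased and female-biased lists; Slc7a13 (1117 against 63.2 CPM) and Slc7a12 (22.5 against 1075 CPM) lie on opposite sides at 6 weeks.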

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

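The test of Kap against free RNA was written before its result was seen, but was prompted by the rise of Kap in all classes.

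Kap, the androgen-responsive gene of the proximal tubule, was found at 7002.42 CPM in the empty droplets of the 6-week library, data that no comparison of the series is built on; a count of 0 would allow 0.104 CPM there. Its level in empty droplets was 70.6 at P0, 850.12 at P7, 1847.33 at P14 and 4671.34 at P21. If free RNA made up the Kap of classes other than proximal tubule, its level there relative to the empty droplets would match the free RNA share of the class, and the median ratio of the 2 over 8 classes and 5 libraries was 0.959 with the lowest share over marker sets, inside the range of 0.5 to 2 set for free RNA, and 0.526 with the median share, where 17 of 40 ratios lay under 0.5 and 0 above 2. Free RNA therefore could account for the level of Kap outside the proximal tubule. At the median share it could account for the level in proximal tubule at 6 weeks too (0.942 times the share). The 650 CPM left there after subtraction rests on the lowest share. Kap in proximal tubule at 6 weeks was at 1381 CPM in nuclei with Y-linked UMIs and 1090 CPM in those with Xist, intervals apart. An equal free RNA share in both sets would not give that difference, and whether the shares were equal was not tested. No biological explanation for Kap was tested.

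Haemoglobin genes were found at 2502.12 CPM in the empty droplets of the P21 library, where a count of 0 would allow 0.0895 CPM, against 701.8 at P0, 1154.04 at P7, 218.24 at P14 and 256.95 at 6 weeks.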

How the results depend on the processing

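Of the 258 named gene and class pairs, all kept their direction and 258 passed with RLE scaling, 257 without an expression filter, 257 with age as rank and 250 with DESeq2. Fewer passed with other nuclei or fewer counts: 240 of 258 with lenient naming, 211 of 223 with 1000 UMIs alone, 202 of 224 at a clustering resolution of 1, 190 of 223 without doublet removal, 160 of 184 at 4000 UMIs, 125 of 163 with each library clustered alone and 129 of 219 after thinning. Without 1 library, 199 of 239 (P0), 103 of 239 (P2), 215 of 257 (P7), 190 of 257 (P14), 141 of 242 (P21) and 93 of 242 (6 weeks) passed. With the empty-droplet profile subtracted 48 of 211 passed, and Spp1 in the thick ascending limb reversed (-0.095). That fit has 5 libraries and fewer degrees of freedom. It lacks P2, so part of the loss comes with leaving out that library. Among all calls of the main fit more reversed after subtraction: 54 of 640 in proximal tubule and 22 of 437 in the distal convoluted and connecting tubule. So did 21 of 800 in principal cells and 20 of 427 in the thick ascending limb. In endothelium, intercalated cells, stroma, the thin limb and urothelium 8, 5, 4, 1 and 0 reversed. Some classes fell under 30 nuclei in a library in the other clusterings and have no value there. Depth limits the tests: thinning every stroma library to the UMI total of the smallest, which held 54 nuclei, left 0 genes past edgeR's test. Of the 925 stroma calls of the main fit, 34 took the other sign after this thinning. The planned limit of 2000 UMIs removes no nucleus. The planned limit of 500 UMIs alone was not run, because it would admit 43768 to 73681 barcodes in 5 libraries, mostly empty droplets. The cause of the moves below was not tested unless named.

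Gene counts in the order principal cells, distal convoluted and connecting tubule, endothelium, intercalated cells, proximal tubule, stroma, thick ascending limb, thin limb and urothelium were 399, 17, 555, 42, 203, 0, 67, 50 and 160 after thinning and 130, 68, 61, 41, 43, 14, 9, 2 and 0 after subtraction. With age as rank the counts were 1267 in principal cells, 665 in the distal convoluted and connecting tubule, 1474 in endothelium, 1179 in proximal tubule, 1737 in stroma, 896 in the thick ascending limb, 553 in the thin limb and 403 in urothelium. With DESeq2 they were 1988 in proximal tubule, 1722 in stroma, 1011 in the thick ascending limb, 438 in the thin limb and 502 in urothelium. Without an expression filter they were 842 in the distal convoluted and connecting tubule, 938 in intercalated cells, 368 in the thin limb and 577 in urothelium. Without doublet removal they were 284 in the distal convoluted and connecting tubule, 553 in stroma and 643 in urothelium. At 4000 UMIs they were 491 in endothelium and 57 in the thin limb. With each library clustered alone they were 1035 in intercalated cells, 367 in proximal tubule, 808 in the thick ascending limb and 99 in urothelium. A clustering resolution of 1 gave 1333 in proximal tubule, and 1000 UMIs alone 1491 in stroma.

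Leaving out 1 library at a time gave 184 to 875 genes in principal cells, 113 to 699 in the distal convoluted and connecting tubule, 354 to 1824 in endothelium, 104 to 578 in intercalated cells, 61 to 326 in proximal tubule, 168 to 1070 in stroma, 20 to 671 in the thick ascending limb, 3 to 703 in the thin limb and 45 to 237 in urothelium. List calls ranged from 40 to 79 for imprinted genes, 10 to 32 for osmolytes, 2 to 22 for antigen presentation, 0 to 55 for cell cycle, 1 to 37 for clock genes, 6 to 49 for hormone response and 1 to 23 for immediate early genes. They ranged from 3 to 11 for water and sodium transport, 1 to 6 for acid-base transport, 1 to 7 for vasa recta, 1 to 3 for thick limb transport, 0 to 8 for the inner medulla, 0 to 3 for injury, 0 to 6 for stromal progenitors and 0 to 1 for matrix. With age as rank the list calls were 32 for osmolytes, 37 for cell cycle, 31 for antigen presentation, 36 for clock genes, 27 for hormone response, 26 for immediate early genes, 2 for proximal transport, 5 for injury and 6 for stromal progenitors. The set tests past went from 48 to 0 with an estimated correlation.

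Trends in shares kept their direction except for endothelium, which reversed without proximal tubule in the denominator (r = 0.1804, adjusted exact permutation p = 0.731) and with 1000 UMIs alone (r = 0.9386, adjusted exact p = 0.0133), and principal cells at 4000 UMIs (r = -0.1594, adjusted exact p = 0.751). With 1000 UMIs alone, trends passed for early nephron stages (r = -0.9322, adjusted exact p = 0.00781), nephron progenitors (-0.9025, 0.0125), the ureteric tip (-0.9588, 0.00781) and the thin limb (0.9319, 0.00781). The stroma trend passed without doublet removal (r = -0.9118, adjusted exact p = 0.0268), at a clustering resolution of 1 (-0.9127, 0.0238) and with lenient naming (-0.9611, 0.0156), and the immune trend at 4000 UMIs (-0.934, 0.0312). The urothelium trend was lost with age as rank (r = 0.8805, adjusted exact p = 0.0536), with libraries clustered alone (0.7154, 0.192) and at 4000 UMIs (0.8382, 0.0896), where that of the thick ascending limb was lost too (0.7948, 0.0896). Without P2 the trends of podocytes (r = -0.9582, adjusted exact p = 0.0625), proximal tubule (0.9683, 0.075) and urothelium (0.9273, 0.125) were lost; with 5 libraries the exact p has a higher floor. By rho, all 6 trends that passed were lost at 4000 UMIs (adjusted exact p = 0.0625 or more), and those of proximal tubule (0.143), podocytes (0.143), the thick ascending limb (0.0833) and urothelium (0.186) with libraries clustered alone. Principal cells passed by rho at a clustering resolution of 1 (0.9856, adjusted exact p = 0.0208), without doublet removal (0.9429, 0.0312) and with 1000 UMIs alone (0.9429, 0.0208). In each of these settings their smallest library held 0 nuclei of the class. Early nephron stages passed by rho with lenient naming (-0.9429, 0.0312). For cycling nuclei, r stayed short of the threshold without doublet removal, with 1000 UMIs alone, unthinned, at 1 or 3 UMIs and without P2, while rho passed on all 6 libraries (exact permutation p = 0.0333) and not without P2 (exact p = 0.0833).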

Other observations

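The comparisons of glucocorticoid genes and of nuclei divided by sex were chosen only after the values were seen; the tests by sex were written after the result, the others before it.

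Further genes moved in principal cells. Smoc2, a matricellular protein gene, fell there from 364 to 2.38 CPM (log2 change -7.18 ± 0.73, SE, n = 6, edgeR adjusted p = 0.00251), and Epor, the erythropoietin receptor, rose there from 1.87 to 54.1 CPM (7.13 ± 0.94, edgeR adjusted p = 0.00601). Malat1, a nuclear noncoding RNA, made up 55482 CPM of all nuclei at P0 and 139595 CPM at 6 weeks.

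Of 16 glucocorticoid and thyroid hormone response genes, 4 picked after their values were seen (Zbtb16, Fkbp5, Per1 and Sgk1) stood higher at P0 than at P2, P7 and P14 and again at P21 and 6 weeks. If free RNA made them, their level in a class would stay at or under 0.25 of that in empty droplets; the median over these 4 genes and 9 classes was 1.405, which speaks against free RNA as a sole source, except for Sgk1, which stood at 0.211 to 0.475 in 5 of the 9 classes. If handling stress of the P0 library made them, immediate early genes would also be higher there. Their median log2 ratio was -0.089, 5 of 15 lay above 0 and 1 (Zfp36) reached 1. As a set these values speak against handling stress that raises immediate early genes at P0. Stress of the mice that raises hormone response genes without them was not tested. At P21 and 6 weeks all 15 lay above 0 (Dusp1 2.57, Zfp36 2.00), so handling stress is not excluded for those ages. Age itself, time of day and a difference between batches of libraries could each give this pattern, and 1 library per age cannot tell them apart.

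The median log2 ratio in the direction of each list was 3.401 at 6 weeks and 0.003 at P21; the rule for it was written after these values, so it does not test whether proximal tubule genes take on the pattern of the sexes between these ages. Free RNA, which both sets of nuclei share, would hold the absolute ratio at or under 0.5, and that was 3.401 too. The 4 mice of each library cannot be told apart, so a single mouse could carry part of this difference.

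For the proximal tubule 60 orders of the ages were run, the real order by design and the others drawn at random with repeats possible. The real order gave 640 genes past edgeR's test and was the only 1 with as many. The highest other order gave 2 and 57 gave 0.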
